A study of Homo sapiens with 60 samples.

How the data were processed

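The study sequenced RNA of HepG2 cells after 24 h with vehicle, wortmannin or 1 of 6 herbal water extracts. Per the labels, libraries were made with a directional kit and sequenced as paired-end reads of 100 bases on an MGI instrument. The authors checked reads with FastQC 0.11.9, trimmed them with Trim Galore 0.6.5, aligned them to hg38 with STAR 2.7.3a and quantified genes with RSEM 1.3.3. The deposited table holds RSEM expected counts per gene, per the labels. Of its values above 0, 76.1% are whole numbers, and the values were rounded to whole counts here. The release of the gene annotation is not given. The table has 270 columns, of which the 60 named in the sample descriptions were used. The other 210 columns were not used here.

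The table lists 60675 genes. Symbols were matched by Ensembl identifier to a table of gene names and to GENCODE v29, which also gave the coordinates on GRCh38. A symbol was found for 41706 genes, and genes without one hold 0.748% of the counts. Total counts per library ran from 20.9 M to 33.4 M. RSEM divides reads shared between similar sequences among them, so counts of close paralogs are not independent. This concerns the MT1 genes, AKR1B10 and the AKR1C genes, GSTA1 and GSTA2, the UGT1A genes, the CYP3A genes, HSPA1A and HSPA1B, and read-through annotations.

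Groups were taken from the sample labels. All 60 libraries were fitted together in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with 1 mean per group, TMM factors (0.926 to 1.03) and filterByExpr with its minimum count of 10 and minimum total of 15. glmQLFit had 40 residual degrees of freedom and a prior of 8.2. Each of 19 groups was tested against vehicle with glmQLFTest. The dose trend was the linear contrast over 20, 100 and 500 µg/mL, equally spaced on the log scale. In this contrast the 100 µg/mL group carries no weight, so the trend compares 500 with 20 µg/mL. A joint test asked whether the 6 trends are equal. Benjamini-Hochberg adjustment was applied within each comparison at a threshold of 0.05, and a prior count of 0.125 was used for fold changes.

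Before the data were examined, 28 gene lists, the rule for named genes, the comparisons and the alternatives were fixed. The lists were aryl hydrocarbon receptor, PXR and CAR, NRF2, ATF4, LXR, PPAR alpha, FOXO, FXR, NF-kB, p53, glucocorticoid receptor and interferon targets, ER chaperones, cholesterol synthesis, fatty acid synthesis, hepatocyte genes, acute phase genes, S phase, mitosis, hypoxia and glycolysis, heat shock, metallothioneins, autophagy and lysosome, ribosomal proteins, mitochondrially encoded genes, and markers of blood cells, of fibroblasts and stellate cells, and of lung and breast epithelial lines. The last list had 3 tested members, fewer than the 5 required, and was not tested. Lists were tested with camera in limma at a preset correlation of 0.01, with adjustment over the 27 lists within a comparison, and again with a correlation estimated for each list. Interferon-stimulated genes and the blood cell markers passed in none of the 13 comparisons. A list's members past the threshold are counted over all genes tested and, separately, adjusted over the list alone.

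The rule for named genes took, for wortmannin, the 10 largest rises and 10 largest falls among genes past the threshold with a symbol, at least 5 CPM in 1 of the groups and no overlap between the libraries of the groups. For each extract it took up to 8 of each at 500 µg/mL against vehicle among genes that also passed over the doses with the same sign. Where fewer than 4 passed, the 4 genes of smallest trend p were added. It further took up to 4 members of each list past its threshold, and 12 genes in every comparison whatever their value, among them CYP1A1, NQO1 and IGFBP1. Genes of lists are given where they help describe the list. ID1 and SMAD7, where given outside that rule, were chosen after their values were seen.

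The alternatives were DESeq2 size factors in the same fit, the DESeq2 1.42.0 Wald test (likelihood ratio for the joint test), a mean of at least 1 CPM in place of the filter, no filter, only the libraries of the groups compared, a regression on log dose over the 9 libraries of an extract, the replicate number as a block, and leaving out each library in turn. Correlations of dose trends were also run as Pearson correlations and over the 9327 genes with a mean of at least 10 CPM.

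The fit was tested on simulated data, drawn from negative binomial distributions with the mean, dispersion and library sizes of the real table and with changes put into 100 genes at each of 1.5-fold and 2-fold. For wortmannin against vehicle, 96 of 100 genes changed 1.5-fold and 97 of 100 changed 2-fold were called, and 4.93% of the calls were false. For the licorice trend the numbers were 82 and 96, with 5.82% false calls. A list of 25 genes raised 1.2-fold was called by camera, and 0 of 20 random lists were. The simulated genes were drawn independently and without differences between sets or replicate numbers. The simulation therefore cannot show how calls hold when genes are correlated. Libraries of a group were checked for shared data by the chi-square per degree of freedom between their counts, which ran from 2.42 to 26.99 over 60 pairs with a median of 5.92, so that no pair was closer than counting error allows.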

Results

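Gene expression was measured by RNA sequencing in 60 libraries of HepG2, an established human hepatocellular carcinoma cell line, after 24 h of treatment. The libraries form 20 groups of 3. One group received the vehicle and one received wortmannin, an inhibitor of phosphoinositide 3-kinase, at 10 µM as the positive control. The other 18 groups received water extracts of 6 medicinal herbs, each at 500, 100 and 20 µg/mL. These were Poria Cocos, Atractylodis Rhizoma, Glycyrrhizae Radix (licorice), Panax Ginseng, Angelicae Gigantis Radix and Paeoniae Radix (peony). They are called Poria, Atractylodes, licorice, ginseng, angelica and peony from here on. The sample labels give the vehicle as 0.1% DMSO, whereas the description of the series gives 2%. The labels of the extract and wortmannin libraries give no DMSO, so a difference in DMSO between them and vehicle is not known.

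Total counts per library ran from 20.9 M to 33.4 M with a median of 26.1 M, so that 3 counts in a library correspond to between 0.09 and 0.144 CPM, counts scaled to the total of the library. After the filter on low counts, 16093 genes were tested. The values are means of 3 libraries, with the SD for CPM and the SE for log2 changes. The p-values measure the spread between libraries, and nothing in the labels says whether the 3 libraries of a group came from separate cultures. Coordinates are on GRCh38.

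The titles of all 60 libraries name the same batch, A. The descriptions of the samples also begin with a number, read here as a set, and what it stands for is not given. Poria and Atractylodes share one, licorice and ginseng share one, and angelica and peony share one. Vehicle begins with A1 and wortmannin with 1, and whether these are the same set is not stated. There is 1 vehicle group, so a comparison of an extract with vehicle cannot be separated from a difference between these sets or in DMSO. For wortmannin the same holds for DMSO, and for the sets unless A1 and 1 mean the same set. The trend over the 3 doses of an extract uses libraries of 1 set and no vehicle library. It is given as log2 of the level at 500 over that at 20 µg/mL. The 100 µg/mL group carries no weight in it, so a trend need not be a steady change over the doses. The share of counts from mitochondrially encoded genes also varied between groups, from a mean of 9% with ginseng at 20 µg/mL to 12.7% with Poria at 100 µg/mL.

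**Figure D1:**
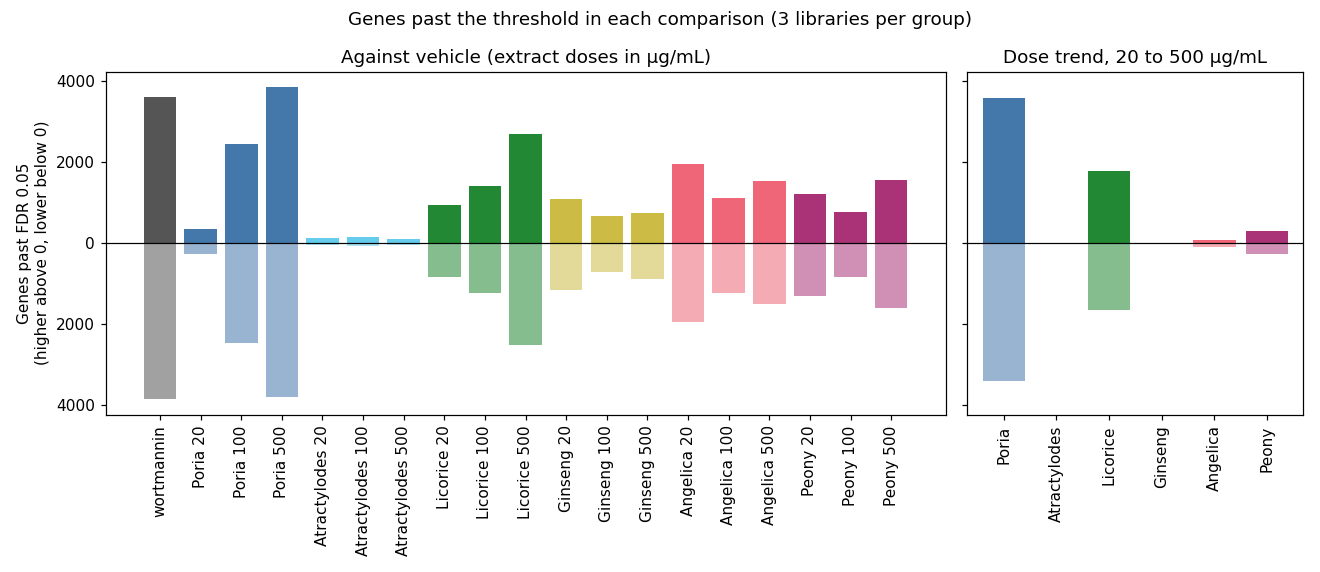
Number of genes past an adjusted p of 0.05 in each comparison, with genes that rose above 0 and genes that fell below 0. The left panel gives each group against vehicle and the right panel the trend from 20 to 500 µg/mL of each extract. Poria (6995) and licorice (3428) have the most genes with a dose trend.

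Wortmannin was compared with vehicle as the positive control. It raised FOXO and gluconeogenesis targets and lowered genes of the cell cycle. DEPP1, a gene induced by FOXO factors, rose 13-fold (log2 3.70 ± 0.095, n = 3), from 12.7 ± 1.67 to 165 ± 9.17 CPM. G6PC1, the catalytic subunit of glucose-6-phosphatase (chromosome 17, 42900797 to 42913369), rose 11.7-fold, from 18.4 ± 2.31 to 216 ± 4.31 CPM. IGFBP1, a secreted binding protein of insulin-like growth factors (chromosome 7, 45888357 to 45893668), rose 9.28-fold, from 129 ± 18.2 to 1196 ± 88.6 CPM. FST, which encodes the activin antagonist follistatin, rose 5.5-fold, and MYO1G, SMPDL3A, the interleukin 6 receptor gene IL6R, CCL16, SPON2 and PLSCR4 rose between 3.22-fold and 3.81-fold. The largest falls were those of DKK1, a secreted inhibitor of Wnt signalling (4.8-fold lower, log2 -2.26 ± 0.081), and of the amino acid transporter gene SLC6A14 (4.22-fold lower).

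All 32 measured members of the list for mitosis and G2/M fell (2.2e-119 as adjusted p, 1.23e-14 with an estimated correlation), with a median log2 change of -1.25. Among them, log2 changes were -1.76 ± 0.052 for CDC20, an activator of the anaphase-promoting complex, -1.65 ± 0.055 for the mitotic kinase PLK1, -1.61 ± 0.057 for cyclin B1 (CCNB1) and -1.46 ± 0.073 for survivin (BIRC5). In S phase and DNA replication, 0 of 33 measured members rose and 31 fell (0 and 31 adjusted over the list alone; adjusted p = 9.99e-45), with log2 changes of -0.91 ± 0.032 for RRM2 and -0.94 ± 0.037 for MCM2. In FOXO and gluconeogenesis targets, 18 of 22 measured members rose and 2 fell (19 and 2 adjusted over the list alone; adjusted p = 5.6e-12), including PPARGC1A at 1.24 ± 0.085. PCK1, the cytosolic phosphoenolpyruvate carboxykinase, changed by 0.90 ± 0.102. In autophagy and lysosome genes, 24 of 31 measured members rose and 1 fell (24 and 1 adjusted over the list alone; adjusted p = 2.66e-10), with WIPI1 at 1.23 ± 0.044 and the protease gene CTSB at 1.10 ± 0.04.

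Some lists of lipid and drug metabolism rose as well. Fatty acid and triglyceride synthesis did not pass (adjusted p = 0.487), with 11 of 20 measured members rising and 7 falling. In cholesterol synthesis and LDL uptake, 12 of 24 measured members rose and 4 fell (13 and 4 adjusted over the list alone). That list passed upward (adjusted p = 0.00462, and adjusted p = 0.132 with an estimated correlation). In PPAR alpha and fatty acid oxidation, 17 of 22 measured members rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 6.43e-06), among them CPT1A, which carries fatty acids into mitochondria (1.27 ± 0.074). In PXR and CAR targets, 9 of 14 measured members rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000664), and in LXR targets 6 of 10 measured members rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.000882). In glucocorticoid receptor targets, 9 of 13 measured members rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.00376), with the kinase gene SGK1 at 1.40 ± 0.065. In p53 targets, 2 of 26 measured members rose and 17 fell (2 and 17 adjusted over the list alone; adjusted p = 0.00143), and in heat shock genes 2 of 18 measured members rose and 11 fell (2 and 11 adjusted over the list alone; adjusted p = 0.000355, and adjusted p = 0.123 with an estimated correlation). The blood cell markers (0.256 as adjusted p) and the fibroblast and stellate markers (0.372) did not pass, nor did mitochondrially encoded genes (0.642), with 0 of 13 past the threshold in edgeR.

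In all, 7456 of 16093 genes (46.3%) passed an adjusted p of 0.05 in edgeR against vehicle, 3599 upward and 3857 downward, and 567 of them changed at least 2-fold. The descriptions begin with 1 for wortmannin and A1 for vehicle, and whether these are the same set is not stated. If they are not, these changes cannot be separated from a difference between the sets. ATP6V1G2-DDX39B, which met the rule for the largest falls (-1.49 ± 0.263), is a read-through annotation that shares its sequence with DDX39B.

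Poria extract gave the most genes of the 6 extracts, both at 500 µg/mL against vehicle and over its doses. Among the largest rises at 500 µg/mL were those of IGFBP3 (11.1-fold, log2 3.47 ± 0.175), IGFBP1 (9.01-fold) and AKR1B10, an aldo-keto reductase (7.95-fold, chromosome 7, 134527592 to 134541408). AKR1B10 stood at 45.9 ± 2.1 CPM with vehicle and at 59.2 ± 4.6, 199.7 ± 9.21 and 365 ± 10.9 CPM with 20, 100 and 500 µg/mL. IGFBP1 stood at 261 ± 60.6, 558 ± 109 and 1161 ± 193 CPM. PLCH2, PFKFB3, a regulator of glycolysis, PHLDA2 and the immediate early gene EGR1 rose between 6.12-fold and 7.46-fold. HAMP, which encodes the iron hormone hepcidin (chromosome 19, 35280716 to 35285143), was 12.4-fold lower than with vehicle, at 0.55 ± 0.236 against 7.06 ± 0.168 CPM, and the metallothionein genes MT1F and MT1G were 10.7-fold and 7.02-fold lower. ALDH8A1, GNMT, a glycine methyltransferase of liver, DTX4, MAB21L4 and GREB1L were between 3.84-fold and 4.3-fold lower.

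With dose, NRF2 antioxidant targets rose: 22 of 26 measured members rose and 1 fell (22 and 1 adjusted over the list alone; adjusted p = 2.22e-50), with a median trend of 0.71. Trends were 1.24 ± 0.035 for GCLC and 1.38 ± 0.051 for GCLM, the subunits of the enzyme that starts glutathione synthesis, and 1.10 ± 0.045 for the quinone reductase NQO1. In hypoxia and glycolysis genes, 27 of 31 measured members rose and 1 fell (29 and 1 adjusted over the list alone; adjusted p = 1.69e-12, and adjusted p = 0.0709 with an estimated correlation), with ENO2 at 1.07 ± 0.059 and the glucose transporter gene SLC2A1 at 0.85 ± 0.061. In autophagy and lysosome genes, 21 of 31 measured members rose and 1 fell (22 and 1 adjusted over the list alone; adjusted p = 2.73e-11), with SQSTM1 at 1.82 ± 0.039. In NF-kB targets, 9 of 17 measured members rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00012), with ICAM1 at 0.82 ± 0.037. ER chaperones were tested against vehicle and over dose. At 500 µg/mL 20 of 24 measured members rose and 0 fell (20 and 0 adjusted over the list alone; adjusted p = 1.99e-07). Over dose 16 of 24 measured members rose and 2 fell (19 and 2 adjusted over the list alone; adjusted p = 0.000142, and adjusted p = 0.0573 with an estimated correlation). HYOU1 trended at 0.38 ± 0.035.

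Cell cycle and lipid synthesis genes fell with the dose of Poria. In mitosis and G2/M, 0 of 32 measured members rose and 31 fell (0 and 31 adjusted over the list alone; adjusted p = 7.4e-26), with TOP2A at -0.72 ± 0.048, and in S phase and DNA replication 1 of 33 measured members rose and 25 fell (1 and 26 adjusted over the list alone; adjusted p = 1.2e-09). In fatty acid and triglyceride synthesis, 1 of 20 measured members rose and 14 fell (2 and 15 adjusted over the list alone; adjusted p = 9.66e-10), with GPAM, which starts glycerolipid synthesis, at -1.05 ± 0.043. In cholesterol synthesis and LDL uptake, 1 of 24 measured members rose and 19 fell (1 and 19 adjusted over the list alone; adjusted p = 7.65e-06), with lanosterol synthase (LSS) at -0.61 ± 0.032. In FXR and bile acid handling, 4 of 11 measured members rose and 6 fell (4 and 6 adjusted over the list alone; adjusted p = 0.0138), with NR1H4, the gene of FXR itself, at -1.45 ± 0.056, while that list did not pass against vehicle (adjusted p = 0.242). In metallothioneins and zinc response, 1 of 9 measured members rose and 7 fell (1 and 7 adjusted over the list alone; adjusted p = 8.94e-06, and adjusted p = 0.0573 with an estimated correlation), and the member that rose was MT2A at 0.70 ± 0.126. MT2A did not pass in a regression on log dose (adjusted p = 0.064).

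Against vehicle, 7659 genes passed at 500 µg/mL in edgeR, 3846 upward and 3813 downward. Over the doses of Poria, 6995 genes passed, 3585 upward and 3410 downward. Poria 100 replicate 1 lay farther from its group than any other library did, with 15.2% of its counts from mitochondrially encoded genes against 11.2% and 11.9% in the other libraries of the group. Without it, 7119 genes passed over the doses, but a 100 µg/mL library carries no weight in the trend itself.

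Atractylodes extract gave few genes with a dose trend. Of 16093 genes, 8 passed in edgeR, 2 upward and 6 downward. Among genes with 5 CPM or more, the 4 of smallest p were G6PC1 (trend -0.58 ± 0.096, adjusted p = 0.00392), AKR1B10 (0.34 ± 0.06, adjusted p = 0.00679), ERG28, a sterol synthesis gene (-0.26, adjusted p = 0.00837), and DEPP1 (-0.55, adjusted p = 0.015). G6PC1 was at 19.6 ± 0.099 CPM with 20 and 13.1 ± 1.74 CPM with 500 µg/mL. Against vehicle, at 500 µg/mL, log2 changes were -0.49 ± 0.096 for G6PC1, 0.24 ± 0.059 for AKR1B10 and -0.52 ± 0.125 for MT2A, while ERG28 (-0.13 ± 0.047) and DEPP1 (0.04 ± 0.11) did not pass. CYP1A1 trended at 0.44 ± 0.089 (adjusted p = 0.0361).

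Small shifts of lists passed over the doses of Atractylodes with 1 or 0 members of a list passing. In cholesterol synthesis and LDL uptake, 0 of 24 measured members rose and 0 fell (0 and 3 adjusted over the list alone; adjusted p = 6.58e-11), with a median trend of -0.07. In metallothioneins and zinc response, 0 of 9 measured members rose and 1 fell (0 and 5 adjusted over the list alone; adjusted p = 5.48e-10), with a median of -0.30. In NRF2 antioxidant targets, 1 of 26 measured members rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 2.07e-06), with a median of 0.09. At 500 µg/mL against vehicle, heat shock genes rose: 7 of 18 measured members rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 6.25e-17), among them CHORDC1 at 0.40 ± 0.054 and HSPA8 at 0.53 ± 0.087. In hypoxia and glycolysis genes, 6 of 31 measured members rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 2.98e-15, and adjusted p = 0.109 with an estimated correlation). Over the doses neither of these 2 lists passed (adjusted p = 0.276 for heat shock, with a median of 0.02, and 0.153 for hypoxia and glycolysis, with a median of -0.02). Against vehicle, the lists for cholesterol synthesis and NRF2 targets did not pass at 500 µg/mL (adjusted p = 0.0657 for each).

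Against vehicle, 143 genes passed at 500 µg/mL in edgeR, 90 upward and 53 downward. The number was 368 without Atractylodes 500 replicate 1, 14 without replicate 2, 12 without replicate 3, 13 without vehicle replicate 2 and 32 without vehicle replicate 3. The number of genes with a dose trend was 4, 1 and 1 without Atractylodes 20 replicates 1, 2 and 3, and 5, 0 and 3 without Atractylodes 500 replicates 1, 2 and 3. The G6PC1 trend was lost without Atractylodes 500 replicate 2 (adjusted p = 0.182), as was its change against vehicle (0.124), which was also lost without Atractylodes 500 replicate 3 (0.069) or vehicle replicate 3 (0.0864). The AKR1B10 change against vehicle was lost without Atractylodes 500 replicate 1 (0.0863), 2 (0.178) or 3 (0.0718) and without vehicle replicate 2 (0.21) or 3 (0.113). Its trend was lost without Atractylodes 20 replicate 2 (0.111) or 3 (0.0572) and without Atractylodes 500 replicate 1 (0.0755) or 2 (0.182). MT2A against vehicle was lost without Atractylodes 500 replicate 2 (0.139) or 3 (0.278) and without vehicle replicate 1 (0.153), 2 (0.0728) or 3 (0.0591). The CYP1A1 trend was lost without Atractylodes 20 replicate 1 (0.0741), 2 (0.487) or 3 (0.0572) and without Atractylodes 500 replicate 1 (0.16), 2 (0.29) or 3 (0.0929).

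Licorice extract raised CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), more than any other named gene in this series. At 500 µg/mL it was 56.2-fold above vehicle (log2 5.81 ± 0.079), at 714 ± 10.3 against 12.7 ± 1.14 CPM. At 20 and 100 µg/mL it stood at 19.9 ± 0.774 and 80.2 ± 5.91 CPM. ALDH3A1 rose 6.04-fold, AKR1B10 4.92-fold, the monocarboxylate transporter gene SLC16A6 4.58-fold, the aquaporin gene AQP3 4.39-fold and SOS1, an exchange factor of RAS, 3.48-fold. AKR1C2 and NQO1 rose 3.37-fold and 2.83-fold. The largest falls were those of PDGFRB, a receptor of platelet-derived growth factor (3.04-fold lower), SLC6A12 (2.58-fold), ARSI, MAB21L4, DKK1 (2.41-fold) and CYP7A1, the rate-limiting enzyme of bile acid synthesis (2.38-fold). PTP4A3 and TRIM50 were 2.31-fold and 2.28-fold lower.

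With dose, 25 of 26 measured NRF2 antioxidant targets rose and 0 fell (25 and 0 adjusted over the list alone; adjusted p = 4.97e-120), with trends of 2.18 ± 0.058 for AKR1B10, 1.39 ± 0.051 for GCLM and 1.05 ± 0.04 for thioredoxin reductase (TXNRD1). In aryl hydrocarbon receptor targets, 7 of 11 measured members rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 1.35e-52), with CYP1A1 at 5.16 ± 0.075 and ALDH3A1 at 2.28 ± 0.137. In PXR and CAR targets, 7 of 14 measured members rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 3.34e-09), with UGT1A1, which conjugates bilirubin, at 1.29 ± 0.062. In ATF4 targets, 11 of 30 measured members rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 1.43e-05), with the cystine transporter gene SLC7A11 at 0.95 ± 0.076. SLC7A11 is also a member of the NRF2 list, and NQO1 of both the NRF2 and the aryl hydrocarbon receptor lists.

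Liver and sterol genes fell with the dose of licorice. In cholesterol synthesis and LDL uptake, 0 of 24 measured members rose and 22 fell (0 and 22 adjusted over the list alone; adjusted p = 4.34e-35), with a median trend of -0.33. HMGCS1, a member of that list, trended at -0.64 ± 0.033. In genes secreted by or marking hepatocytes, 3 of 27 measured members rose and 18 fell (3 and 18 adjusted over the list alone; adjusted p = 3.66e-12), with albumin (ALB) at -0.49 ± 0.054 and the fibrinogen gene FGB at -0.42 ± 0.035. In FXR and bile acid handling, 0 of 11 measured members rose and 6 fell (0 and 8 adjusted over the list alone; adjusted p = 0.000241), with CYP7A1 at -0.89 ± 0.126. In acute phase genes, 3 of 15 measured members rose and 6 fell (4 and 7 adjusted over the list alone; adjusted p = 0.00117, and adjusted p = 0.125 with an estimated correlation), and in hypoxia and glycolysis genes 0 of 31 measured members rose and 15 fell (1 and 19 adjusted over the list alone; adjusted p = 2.05e-08, and adjusted p = 0.141 with an estimated correlation), with CA9 at -2.03 ± 0.24. Against vehicle, at 500 µg/mL of licorice, the hypoxia and glycolysis list did not pass and leaned upward (10 members rose and 3 fell, median 0.10; adjusted p = 0.185). In the list of fibroblast and stellate markers, 0 of 7 measured members rose and 5 fell (0 and 6 adjusted over the list alone; adjusted p = 1.39e-06), and these 7 members have tested counts in HepG2 itself. Its members PDGFRB and FN1 trended at -1.44 ± 0.112 and -0.37 ± 0.058, and FN1 stood at 9913 ± 662 CPM with vehicle.

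Against vehicle, 5213 genes passed at 500 µg/mL in edgeR, 2693 upward and 2520 downward. Over the doses of licorice, 3428 genes passed, 1768 upward and 1660 downward. Members of the AKR1C and UGT1A families share sequence, so that counts can move between paralogs.

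**Figure D2:**
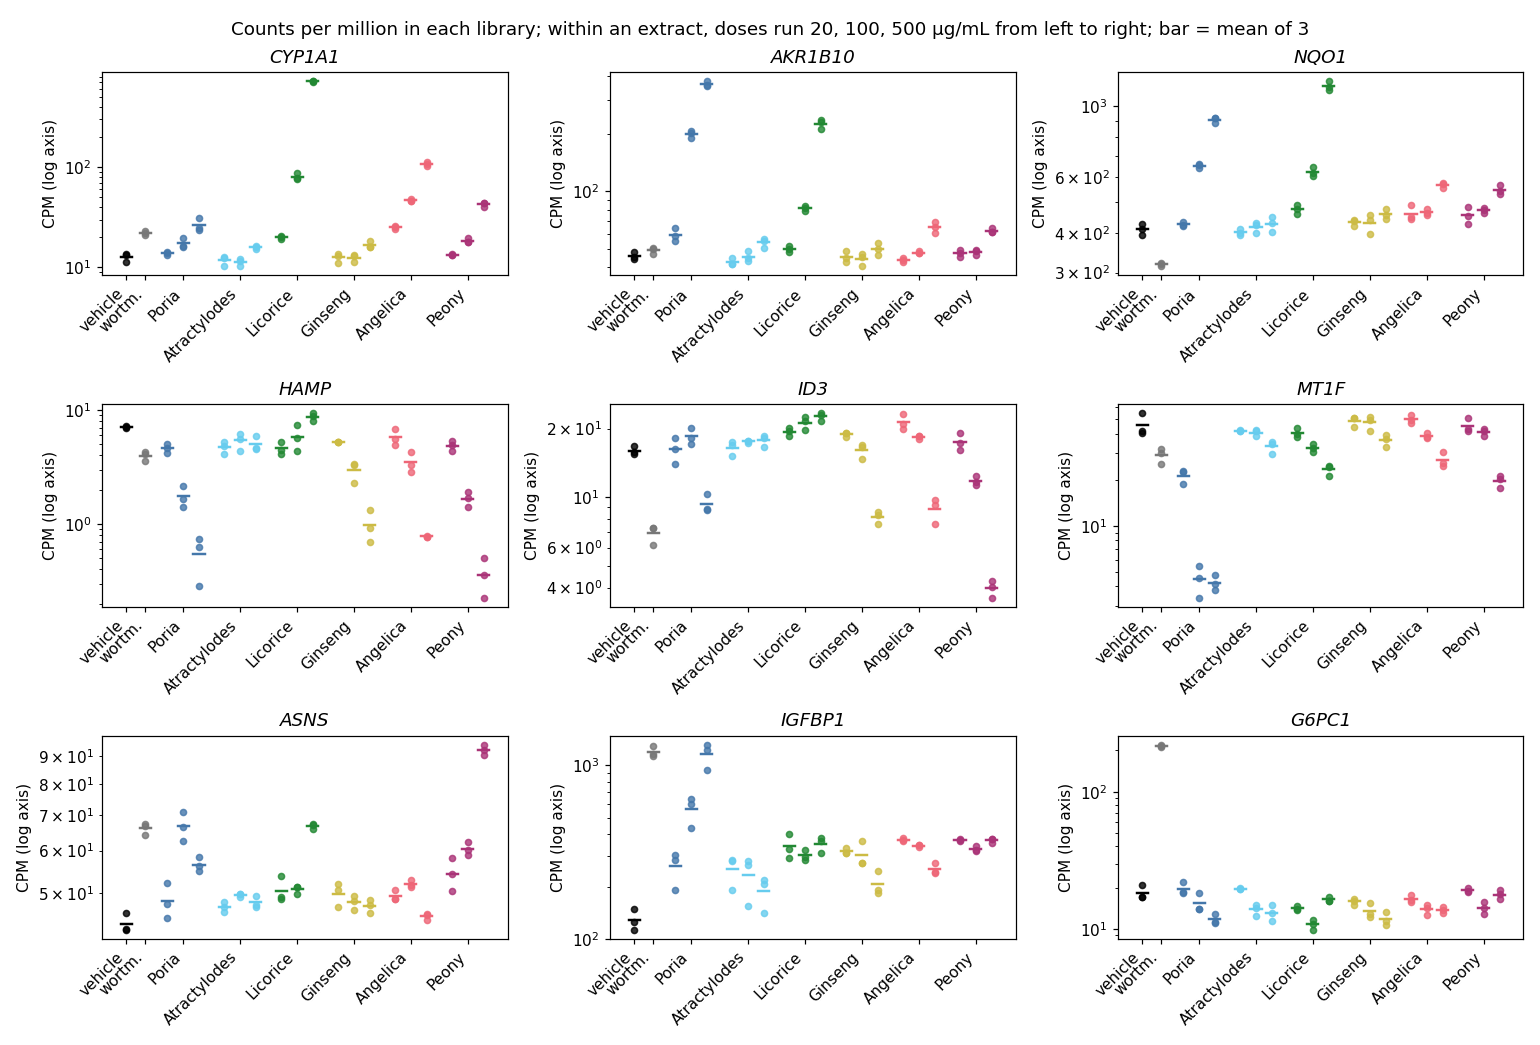
CPM of 9 genes in each of the 60 libraries on a log axis, with 1 point per library and a bar at the mean of 3. Within an extract the doses run from 20 to 500 µg/mL. With licorice CYP1A1 goes from 19.9 to 714 CPM, and with peony HAMP goes from 4.85 to 0.359 CPM.

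Ginseng extract lowered HAMP with dose, at 5.22 ± 0.0376, 2.96 ± 0.596 and 0.981 ± 0.327 CPM with 20, 100 and 500 µg/mL (trend -2.40 ± 0.212). At 500 µg/mL HAMP was 7.15-fold below vehicle. ID3, an inhibitor of basic helix-loop-helix factors (chromosome 1, 23557918 to 23559794), fell from 18.9 ± 0.402 to 8.17 ± 0.491 CPM over the doses and was 1.96-fold below vehicle at 500 µg/mL. SMAD7, an inhibitory SMAD, and SEMA3B, PAQR8, FZD4, DGKK and MT1F were between 1.26-fold and 1.39-fold below vehicle at 500 µg/mL. CYP1A1 (log2 0.41 ± 0.086), the mannose-binding lectin gene MBL2 (0.31 ± 0.051) and TIMP3, an inhibitor of metalloproteinases (0.18 ± 0.037), were higher than with vehicle. The MT1F change against vehicle was lost without Ginseng 500 replicate 3 (adjusted p = 0.128) or vehicle replicate 1 (0.268).

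Over the doses, lists of sterol and metal genes shifted by small amounts. In cholesterol synthesis and LDL uptake, 0 of 24 measured members rose and 2 fell (0 and 15 adjusted over the list alone; adjusted p = 6.59e-27), with a median trend of -0.11. In metallothioneins and zinc response, 0 of 9 measured members rose and 2 fell (0 and 7 adjusted over the list alone; adjusted p = 3.33e-17), with a median of -0.43. In fatty acid and triglyceride synthesis, 0 of 20 measured members rose and 2 fell (0 and 5 adjusted over the list alone; adjusted p = 1.22e-13), with ACSS2, which makes acetyl-CoA from acetate, at -0.32 ± 0.04. In acute phase genes, 0 of 15 measured members rose and 1 fell (0 and 2 adjusted over the list alone; adjusted p = 3.97e-05, and adjusted p = 0.0594 with an estimated correlation), and the member that fell was HAMP, while the list did not pass against vehicle (adjusted p = 0.319). Against vehicle, at 500 µg/mL, ER chaperones rose: 13 of 24 measured members rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 2.12e-10), with HERPUD1 at 0.56 ± 0.08. In heat shock genes, 10 of 18 measured members rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 1.73e-11), and in hypoxia and glycolysis genes 17 of 31 measured members rose and 0 fell (22 and 0 adjusted over the list alone; adjusted p = 2.56e-15, and adjusted p = 0.0791 with an estimated correlation). Over the doses, ER chaperones (0.648 as adjusted p) and heat shock genes (0.056) did not pass. Hypoxia and glycolysis genes passed downward over the doses, against their direction from vehicle, with a median of -0.05 (adjusted p = 0.00482, and adjusted p = 0.53 with an estimated correlation).

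Against vehicle, 1648 genes passed at 500 µg/mL in edgeR, 750 upward and 898 downward, and 24 passed over the doses, 4 upward and 20 downward. The count against vehicle was 865 and 1035 without Ginseng 500 replicates 2 and 3, and 1018 and 881 without vehicle replicates 2 and 3. The count over the doses was 13, 11 and 8 without Ginseng 20 replicates 1, 2 and 3, and 8 and 10 without Ginseng 500 replicates 1 and 3. The MT1X trend was lost without any 1 of the Ginseng 20 and 500 libraries (adjusted p from 0.0663 to 0.369 in edgeR). The MT1F trend was lost without each Ginseng 20 library, Ginseng 500 replicate 1 or 3, or Ginseng 100 replicate 2 (0.0501 to 0.494). Without Ginseng 500 replicate 1, the trends of HMGCS1 (0.102), LSS (0.321) and FADS2 (0.444) were lost. The CYP1A1 trend was lost without Ginseng 20 replicate 1 or 3 or Ginseng 500 replicate 2.

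Angelica extract raised CYP1A1 with dose and lowered HAMP and metallothionein genes. CYP1A1 stood at 25.2 ± 0.915, 46.6 ± 1.15 and 108 ± 5.52 CPM with 20, 100 and 500 µg/mL, and was 8.5-fold above vehicle at 500 µg/mL (log2 3.09 ± 0.076). UGT1A1 was 1.76-fold and MBL2 1.62-fold above vehicle, and UNC93A, LINC02015, PIR, the claudin gene CLDN2 and AKR1B10 were between 1.42-fold and 1.72-fold above it. HAMP was 9.03-fold below vehicle, at 0.778 ± 0.0067 CPM, and ID3 1.8-fold below it. MT1F, MT1G, MT1X, the protease gene FURIN, PAQR8 and SMAD7 were between 1.43-fold and 1.71-fold below vehicle.

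Over the doses, in metallothioneins and zinc response 0 of 9 measured members rose and 7 fell (0 and 8 adjusted over the list alone; adjusted p = 2.16e-33), with a median trend of -0.81, and with MT1G at -1.002 ± 0.126 and MT2A at -0.89 ± 0.125. In aryl hydrocarbon receptor targets, 3 of 11 measured members rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 1.89e-21), with CYP1A1 at 2.10 ± 0.07 and ALDH3A1 at 0.85 ± 0.151. In PXR and CAR targets, 4 of 14 measured members rose and 0 fell (6 and 1 adjusted over the list alone; adjusted p = 6.81e-07), with UGT1A1 at 0.61 ± 0.064 and the glutathione transferase gene GSTA2 at 0.46 ± 0.081. In NRF2 antioxidant targets, 8 of 26 measured members rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 3.03e-18), with AKR1B10 at 0.57 ± 0.059. In cholesterol synthesis and LDL uptake, 0 of 24 measured members rose and 13 fell (0 and 21 adjusted over the list alone; adjusted p = 8.03e-32), with LSS at -0.25 ± 0.032. Against vehicle, ribosomal protein genes were higher at 500 µg/mL: 28 of 50 measured members rose and 0 fell (37 and 0 adjusted over the list alone; adjusted p = 1.12e-12, and adjusted p = 0.188 with an estimated correlation). Over the doses of angelica they did not pass (adjusted p = 0.661), with 0 of 50 past the threshold in edgeR.

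Against vehicle, 3045 genes passed at 500 µg/mL in edgeR, 1530 upward and 1515 downward. Over the doses of angelica, 196 genes passed, 86 upward and 110 downward. The count against vehicle was 1776 without vehicle replicate 3. The count over the doses was 126 and 112 without Angelica 20 replicates 2 and 3, and 122 and 124 without Angelica 500 replicates 2 and 3.

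Peony extract lowered HAMP and raised genes of the integrated stress response. HAMP was 19.8-fold below vehicle at 500 µg/mL (log2 -4.31 ± 0.242) and stood at 4.85 ± 0.486, 1.66 ± 0.238 and 0.359 ± 0.138 CPM with 20, 100 and 500 µg/mL. Its HAMP trend did not pass a test of difference from that of Poria (adjusted p = 0.191), ginseng (0.126) or angelica (0.42). ID3 was 4.01-fold below vehicle, at 3.97 ± 0.338 CPM, and ID1 1.93-fold below it. MT1F, MT1G and MT1X were 2.33-fold, 2.3-fold and 2.04-fold lower, and GREB1L and ANKRD1 1.84-fold and 1.82-fold lower. CYP1A1 was 3.34-fold above vehicle, SLC7A11 2.34-fold, the stress gene DDIT4 2.27-fold and ASNS, which makes asparagine, 2.11-fold. NUPR1, JDP2 and INHBE were between 1.81-fold and 1.95-fold above vehicle.

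Over the doses, in ATF4 integrated stress response targets 19 of 30 measured members rose and 0 fell (24 and 0 adjusted over the list alone; adjusted p = 5.2e-54), with ASNS at 0.77 ± 0.045, the folate enzyme gene MTHFD2 at 0.40 ± 0.043 and SLC6A9 at 0.56 ± 0.064. In metallothioneins and zinc response, 0 of 9 measured members rose and 8 fell (1 and 8 adjusted over the list alone; adjusted p = 2.3e-42), with a median trend of -1.08 and MT1G at -1.47 ± 0.13. In heat shock genes, 0 of 18 measured members rose and 11 fell (0 and 14 adjusted over the list alone; adjusted p = 1.62e-21), with FKBP4 at -0.29 ± 0.036, and in ER chaperones 0 of 24 measured members rose and 9 fell (1 and 11 adjusted over the list alone; adjusted p = 1.98e-12), with HSPA5, the chaperone BiP, at -0.29 ± 0.036. Against vehicle, at 500 µg/mL of peony, neither list passed, with a median log2 change of 0.01 for heat shock genes (4 members rose and 3 fell; adjusted p = 0.655) and 0.009 for ER chaperones (5 rose and 4 fell; adjusted p = 0.688). In glucocorticoid receptor targets, 0 of 13 measured members rose and 3 fell (0 and 5 adjusted over the list alone; adjusted p = 2.41e-09), and the members that fell were MT1X, MT2A and SGK1, while the list did not pass against vehicle (adjusted p = 0.185). In cholesterol synthesis and LDL uptake, 0 of 24 measured members rose and 8 fell (0 and 17 adjusted over the list alone; adjusted p = 8.86e-18). In aryl hydrocarbon receptor targets, 3 of 11 measured members rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 3.79e-10). Against vehicle, the same list passed upward (adjusted p = 0.000714) with a mean log2 change of 0.25 but a median of -0.05.

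Hypoxia and glycolysis genes were higher than with vehicle at 500 µg/mL of peony: 28 of 31 measured members rose and 0 fell (29 and 0 adjusted over the list alone; adjusted p = 1.86e-30), with VEGFA at 0.58 ± 0.051. Over the doses of peony, 6 of 31 measured members rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 2.27e-05, and adjusted p = 0.309 with an estimated correlation), with a median trend of 0.08. S phase and DNA replication genes were lower than with vehicle at 500 µg/mL of peony: 0 of 33 measured members rose and 18 fell (0 and 20 adjusted over the list alone; adjusted p = 2.15e-14), with MCM3 at -0.34 ± 0.03. Over its doses, 0 of 33 measured members rose and 8 fell (1 and 10 adjusted over the list alone; adjusted p = 6.5e-05), with a median trend of -0.05. Against vehicle, 3164 genes passed at 500 µg/mL in edgeR, 1558 upward and 1606 downward. Over the doses of peony, 561 genes passed, 287 upward and 274 downward. The count over the doses was 323 without Peony 20 replicate 2, and 341, 355 and 350 without Peony 500 replicates 1, 2 and 3.

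**Figure D3:**
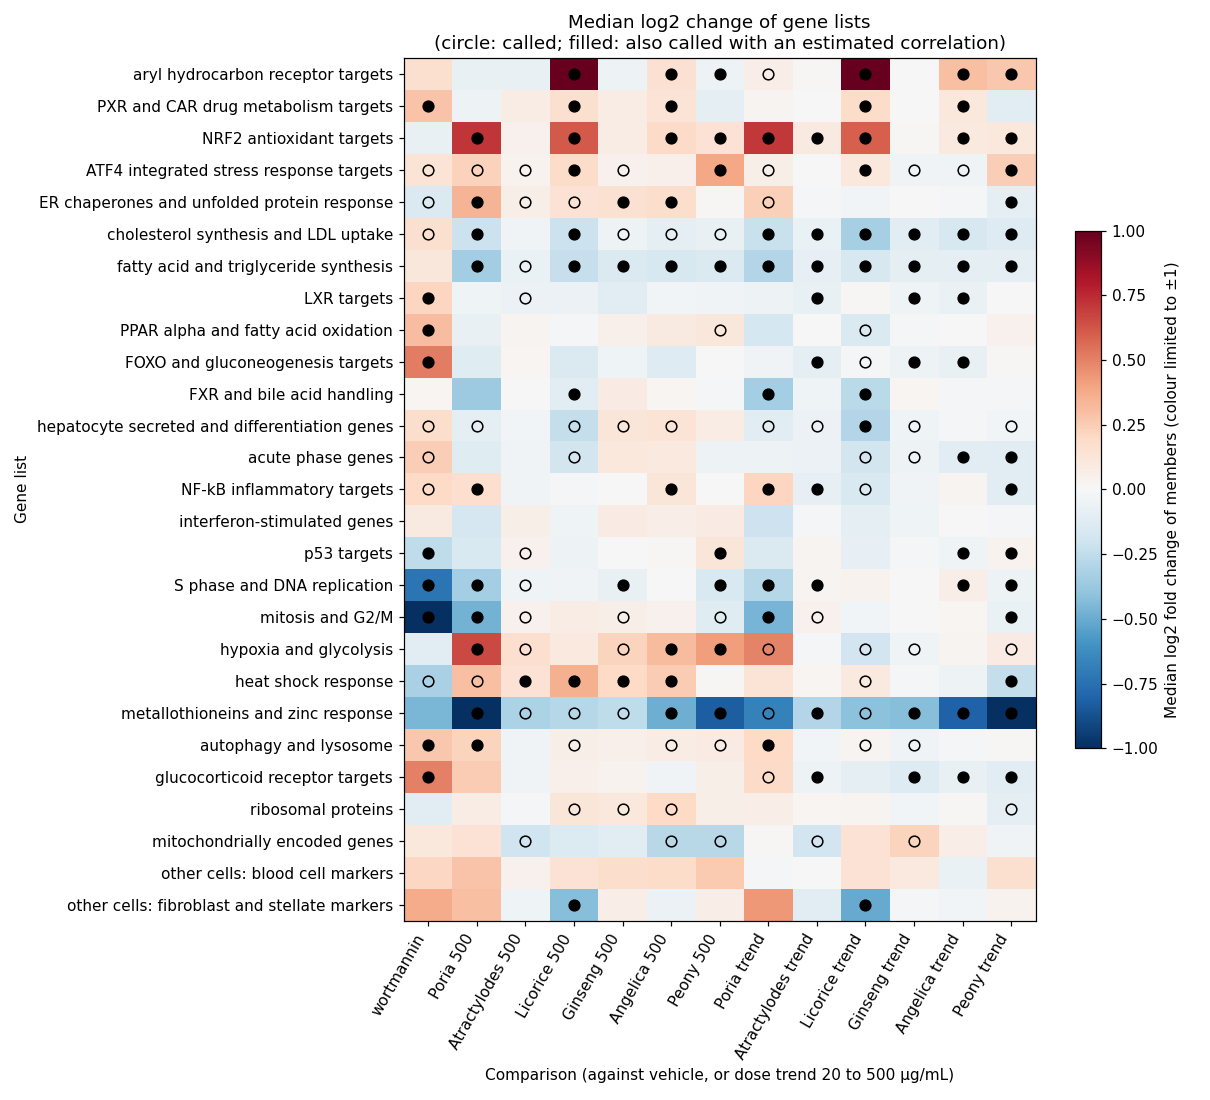
Median log2 change of the members of 27 gene lists in wortmannin against vehicle, in each extract at 500 µg/mL against vehicle, and over the doses of each extract. Circles mark lists past an adjusted p of 0.05, filled where the call also holds with a correlation estimated for each list. The darkest blue cell of wortmannin is the list for mitosis and G2/M, with a median of -1.25.

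IGFBP1 stood at 129 ± 18.2 CPM with vehicle and at 261 ± 60.6, 252 ± 53.9, 342 ± 56.7, 319.6 ± 13.5, 372 ± 6.59 and 371 ± 4.49 CPM with 20 µg/mL of Poria, Atractylodes, licorice, ginseng, angelica and peony. With Poria it rose with dose (2.15 ± 0.17), while its trends with the other 5 extracts, in that order, were -0.43 ± 0.167, 0.05 ± 0.165, -0.62 ± 0.167, -0.56 ± 0.166 and -0.004 ± 0.164 and did not pass. With ginseng and angelica the adjusted p was 0.157 and 0.082, and every library at 500 µg/mL lay below every library at 20 µg/mL. With Atractylodes, IGFBP1 was lower at 500 than at 20 µg/mL within each replicate number. Replicates 1, 2 and 3 stood at 140, 206 and 217 CPM with 500 µg/mL and at 190, 282 and 285 CPM with 20 µg/mL. The test did not use that pairing. The number of genes past the threshold in edgeR at 100 and 20 µg/mL against vehicle was 4902 and 611 for Poria, 217 and 174 for Atractylodes, and 2645 and 1798 for licorice. It was 1373 and 2232 for ginseng, 2352 and 3914 for angelica, and 1617 and 2537 for peony.

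These counts at 100 and 20 µg/mL rest in part on single libraries. Without vehicle replicate 1 they were 321 for Poria 20, 142 for Atractylodes 100 and 79 for Atractylodes 20. Without vehicle replicate 2 they were 232 for Poria 20, 62 for Atractylodes 100, 30 for Atractylodes 20, 1054 for Licorice 20 and 813 for Ginseng 100. Without vehicle replicate 3 they were 85 for Atractylodes 100, 1673 and 1091 for Licorice 100 and 20, 722 and 1314 for Ginseng 100 and 20, 1342 and 2557 for Angelica 100 and 20, and 948 and 1505 for Peony 100 and 20. Leaving out replicate 1 of its own group gave 432 for Atractylodes 100, 363 for Atractylodes 20, 2308 for Ginseng 100, 1127 for Ginseng 20, 1449 for Angelica 100 and 993 for Peony 100. Leaving out its replicate 2 gave 318 for Poria 20, 30 for Atractylodes 100, 25 for Atractylodes 20, 1695 for Licorice 100, 733 for Licorice 20, 486 for Ginseng 100 and 1192 for Peony 20. Leaving out its replicate 3 gave 146 for Poria 20, 12 for Atractylodes 100, 25 for Atractylodes 20, 557 for Ginseng 100 and 1831 for Angelica 20.

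The extracts differed in their dose trends. A joint test of the 6 trends for equality passed for 5647 of 16093 genes (35.1%) in edgeR. HAMP trended at 0.92 ± 0.152 with licorice and at -3.77 ± 0.259 with peony, a difference of 4.69 ± 0.304 (adjusted p = 3.4e-17). PDGFRB rose with the dose of Poria (0.996 ± 0.087) and fell with that of licorice (-1.44 ± 0.112), with an adjusted p of 3.92e-19 for the difference. PFKFB3 trended at 1.35 ± 0.278 with Poria and -1.35 ± 0.317 with licorice (adjusted p = 1.42e-06). NUPR1, a stress gene, trended at -1.17 ± 0.116 with Poria and 0.67 ± 0.087 with peony (adjusted p = 1.52e-14). The trend of AKR1B10 was higher with Poria than with licorice by 0.45 ± 0.079 (adjusted p = 1.26e-05).

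Between pairs of extracts, the number of genes whose trends differed ran from 4, for ginseng against both Atractylodes and angelica, to 5124 for Poria against peony. For Poria against licorice, trends differed in 4155 genes, and in 408 of them both trends passed in opposite directions. Across genes, the trends of Poria and licorice had a Spearman correlation of 0.277, against a highest value of 0.217 in 100 draws with the doses permuted within each extract. Atractylodes and angelica had one of 0.134, against a highest value of 0.123, and it was 0.009 as a Pearson correlation. The other 19 of the 21 correlations, including all 6 with the wortmannin change, lay within the range of the permuted draws. These correlations are across genes, which are not independent replicates, so no p is given.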

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

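The tests of the fall in HAMP, ID1, ID3 and SMAD7 and the counts of other splits of the libraries were chosen after the results they measure were seen. The remaining tests were fixed before their results were seen, except the direct contrast used against an effect of equal size, which was not fixed for that explanation.

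The 6 extracts differed in the dose trend of 5647 genes by a joint test of the difference. The following named genes passed in opposite directions in a pair of extracts, with the difference of the trends on the log2 scale tested itself. HAMP differed by 4.69 between licorice and peony, ID3 by 2.36 and UNC93A by -1.56 between the same extracts. PFKFB3 differed by 2.695, PDGFRB by 2.44, ARSI by 1.503, SPON2 by 1.31, PCK1 by 1.22, CLDN2 by 0.777, TXNIP by 0.584 and CDC20 by -0.469 between Poria and licorice. NUPR1 differed by -1.83, MT2A by 1.74, JDP2 by -1.29, ANKRD1 by 1.26 and INHBE by -0.919 between Poria and peony. DEPP1 differed by 1.84 and FST by 1.35 between Poria and angelica, and TIMP3 by -0.598 between licorice and angelica. Each is the first extract minus the second, and the adjusted p of the differences in edgeR ran from 2.18e-20 to 0.000484 over all 44 such pairs. The pairs were chosen for trends that passed with opposite signs, which makes a passing difference likely, so these p-values are no separate support.

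HAMP, ID1, ID3 and SMAD7 fell together with the dose of ginseng, angelica and peony, with peony trends of -3.77, -1.47, -2.14 and -0.77. Of these genes, 4 of 4 lay below the 2.5th percentile of the 100 genes nearest in mean CPM. HAMP compares with a lowest matched trend of -0.51, ID1 with -0.278, ID3 with -0.264 and SMAD7 with -0.383. Choosing the genes for their fall makes both the percentile and the distance likely, so this comparison cannot test low counts as the source. Their peony trends passed in edgeR over all genes tested, with adjusted p from 2.08e-22 for ID3 to 9.63e-08 for SMAD7. The 4 genes are known targets of BMP signalling through SMAD factors, and lower BMP-SMAD signalling is a candidate explanation. Of 5 further targets listed before their values were looked at, SMAD6, SMAD9 and BAMBI had tested counts, with a median peony trend of -0.328 and a camera p of 0.00454 (0.0272 adjusted over the 6 extracts, 0.00659 unadjusted with an estimated correlation), a list below the 5 members required elsewhere, a rule set aside here. In ginseng and angelica that p was 0.0535 and 0.0542, and in Poria, where the 4 genes fell too, it was 0.81. With Poria BAMBI passed upward (0.261, adjusted p = 0.0316 in edgeR). With licorice SMAD9 passed downward (-0.367, adjusted p = 0.000424) while HAMP rose (0.924). HAMP and ID3 were also lower with wortmannin than with vehicle. Its libraries ran from 3.53 to 4.24 CPM for HAMP, against 6.9 to 7.24 CPM with vehicle. For ID3 they ran from 6.15 to 7.34 CPM, against 15.4 to 16.8 CPM. ID1 and SMAD7 are not given for wortmannin. The explanation rests on SMAD6 (-0.521, adjusted p = 0.0211) and BAMBI (-0.328, adjusted p = 0.0494) in peony, as SMAD9 did not pass there (-0.048, adjusted p = 0.852), and stays open.

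With angelica, 3914 genes passed against vehicle at 20 µg/mL and 196 over the doses, and ginseng and peony showed the same imbalance (2232 and 24, 2537 and 561). Without Angelica 20 replicate 3 these counts were 1831 and 112, and without Peony 20 replicate 2 they were 1192 and 323. Without Ginseng 20 replicate 1 they were 1127 and 13. Deviations of the angelica and peony libraries named had the strongest correlations with exonic length of all 60 (-0.382 and -0.361). Whether a bias of these libraries raised the counts at 20 µg/mL was not tested. An effect of equal size of all 6 extracts, without a set difference, is argued against by the direct contrast of Atractylodes and angelica at 20 µg/mL. In it 2833 genes differed, but it was not the test fixed for this explanation. The test fixed was the median ratio of their changes over the 3914 genes, 0.253 (quartiles 0.037 and 0.497). That ratio is lowered by the choice of genes called with angelica and is not used as an argument. For a difference between the numbered sets, 20 µg/mL groups of different sets differed in a median of 410.5 genes, against at most 11 for groups of 1 set. This met the prediction, but 6 extracts can be paired in only 15 ways, too few for a share under 0.05. The pairs of different sets ran from 0 to 3509 genes. That test rests on Poria and Atractylodes against the other sets, since licorice and ginseng differed from angelica and peony in 0 to 30 genes. Licorice differed from Poria and Atractylodes in 67 and 23 genes, whereas ginseng, of the same set as licorice, differed from them in 1772 and 754. Licorice 20 replicate 1 lay apart from its group, with 10.7% of counts from mitochondrially encoded genes against 8.1% and 8.6%. Its chi-square per degree of freedom was 16.41 and 9.93 against replicates 2 and 3, which had 4.82 between them. These pairs were not tested without that library. The test therefore does not decide for a set difference. With 1 vehicle group, a set difference that the vehicle lacks and an effect of the extracts at 20 µg/mL both stay open, as does a difference in DMSO, which the labels of the extracts do not give.

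Poria 100 replicate 1 deviated from the other libraries of its group by a root mean square of 0.52 on the log2 scale, against a median of 0.324 over all libraries and 0.4 for the next. A different effective dose is argued against by a Spearman correlation of -0.147 across genes between its deviation and the Poria trend. A bias with gene length is argued against by a correlation of -0.088 with exonic length. Among its largest deviations are read-through or duplicated loci, such as BLOC1S5-TXNDC5 (5.06) and EIF3CL (-4.52). How reads were divided between overlapping annotations was not tested, and no biological explanation was tested.

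Other splits of the libraries were counted in fits of only the libraries compared. Over 100 splits drawn of the 9 libraries of an extract, the real doses gave more genes than every other split for Poria (5915 against at most 1541), licorice (3158 against 1308), angelica (94 against 40) and peony (377 against 261). In each of these 1 of 100 splits, the real one, gave as many, which argues against a random grouping as the source. The draws cover 100 of 840 possible splits and were chosen after the counts were seen, so they do not exclude it. For Atractylodes and ginseng, 3 of 100 splits gave as many as the real 10 and 13 genes, and the highest of the others gave 123 and 153. Such counts, several times the real one, point to a structure of these samples, which was not tested. For the joint test, 1 of 40 splits gave as many as the real 5527, and the highest of the others gave 289.

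Against vehicle, 3 libraries against 3 allow 10 splits, too few for a share under 0.05, and in each comparison 1 split gave as many genes, the real one. The real count and the highest other were 7631 and 1 for wortmannin. For 500, 100 and 20 µg/mL they were 7499 and 0, 3415 and 0, and 201 and 17 for Poria, and 86 and 2, 36 and 7, and 123 and 0 for Atractylodes. They were 5116 and 0, 2372 and 1, and 1053 and 0 for licorice, and 1384 and 1, 334 and 9, and 2462 and 0 for ginseng. They were 3203 and 1, 2629 and 1, and 2285 and 1 for angelica, and 3525 and 2, 2159 and 1, and 1167 and 1 for peony.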

How the results depend on the processing

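The alternatives were fixed before the data were examined. Of the 665 calls of named genes, none reversed its direction, and of the 179 list calls, none passed in the opposite direction. Lists that lost their call were not followed for direction. Of the 21 correlations of trends, 4 changed sign. Genes outside the named ones were not followed for reversal. With DESeq2 size factors each count of genes stayed within 1.5 times its value, and the calls of 0 of 179 list tests and 3 of 665 named genes were lost. Calls of named genes were lost for 3 with the DESeq2 Wald test, 2 of 660 with a mean of at least 1 CPM, 23 without a filter, 29 with only the groups compared and 29 of 232 with a regression on log dose. Leaving out 1 library ended 33 of 179 list calls and 75 of 665 gene calls.

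With only the groups compared, which leaves fewer libraries to estimate the spread, counts against vehicle were 201 for Poria 20, 86 and 36 for Atractylodes 500 and 100, 1053 for Licorice 20, 334 for Ginseng 100, 2285 for Angelica 20 and 1167 for Peony 20, and trend counts were 13 for ginseng and 94 for angelica. Without a filter, counts were 331, 383 and 360 for Atractylodes 500, 100 and 20 against vehicle, and 90, 114 and 315 for the trends of Atractylodes, ginseng and angelica. The DESeq2 Wald test gave 215 for Atractylodes 500 and trends of 15 for Atractylodes and 37 for ginseng. Regression on log dose gave 13 for ginseng, 96 for angelica and 350 for peony. The cause was not tested for the last 3 settings.

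With an estimated correlation, lists past the threshold numbered 9 for wortmannin, 1, 9, 4, 9 and 8 for Atractylodes, licorice, ginseng, angelica and peony at 500 µg/mL, and 8, 9 and 6 for the trends of Poria, licorice and ginseng. In all, 71 of 179 list calls were lost. With the replicate number as a block, no count of genes moved by over 1.5 times (wortmannin 7521, Poria trend 7073), and 1 list call and 2 gene calls were lost. That block fits 1 effect per number for all sets together, so it cannot test a pairing within a set. The deviations of log2 CPM from the group mean had a mean correlation of 0.036 between groups of 1 set for the same replicate number and -0.018 for different numbers, and 0 of 190 pairs of groups had every correlation above 0.1, so the numbers were not used to pair the libraries. The 190 pairs include groups of different sets, for which the mean for the same number was 0.002. Against leaving the numbers out, 38 of 54 libraries correlated best with their own number, of 3 numbers, within their set. IGFBP1 was also lowest in replicate 1 in every group of Poria and Atractylodes. Both are a hint from the data that libraries of a number share something. No pairing within a set was fitted, so any spread shared by libraries of a number stays in the SEs.

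As Pearson correlations, trends correlated at 0.039 and 0.129 for Poria with angelica and peony, 0.045 and 0.009 for Atractylodes with licorice and angelica, 0.042 and -0.052 for ginseng with angelica and peony, and -0.016 and 0.002 for wortmannin with Atractylodes and peony. The sign changed for ginseng with peony (0.11 as Spearman), for wortmannin with Poria (0.008 and -0.011), for Poria with Atractylodes (0.008 and -0.023) and for Atractylodes with peony (-0.025 and 0.012). Over genes with at least 10 CPM they were 0.243, 0.15 and 0.269 for Atractylodes with licorice, ginseng and angelica, 0.289 for licorice with angelica, 0.357 and 0.211 for ginseng with angelica and peony, and 0.106, -0.335, -0.255 and 0.25 for wortmannin with Poria, Atractylodes, angelica and peony. The cause was not tested.

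Leaving out 1 library at a time gave 6743 to 7055 genes for wortmannin. For 500, 100 and 20 µg/mL the ranges were 6870 to 7154, 4063 to 4435 and 146 to 682 for Poria, 12 to 368, 12 to 432 and 25 to 363 for Atractylodes, 4216 to 4703, 1673 to 2313 and 733 to 1929 for licorice, 865 to 1490, 486 to 2308 and 1127 to 1848 for ginseng, 1776 to 2594, 1342 to 2006 and 1831 to 4063 for angelica, and 2286 to 2601, 948 to 1266 and 1192 to 2515 for peony. Trend counts ran from 6065 to 7119 for Poria, 0 to 8 for Atractylodes, 2733 to 3415 for licorice, 8 to 30 for ginseng, 112 to 217 for angelica and 323 to 546 for peony, and the joint test from 5100 to 5858. Lists past the threshold ran from 15 to 16 for wortmannin, at 500 µg/mL from 13 to 14, 9 to 12, 14 to 15, 9 to 12, 14 to 15 and 12 to 14 for the 6 extracts in the order above, and over the doses from 14 to 17, 12 to 15, 14 to 17, 8 to 14, 12 to 13 and 16 to 18.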

Other observations

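Among the 12 genes followed in every comparison, PCK1, a gene of gluconeogenesis, was higher than vehicle at 500 µg/mL of Poria (log2 1.04 ± 0.103), ginseng (0.59 ± 0.105), angelica (0.66 ± 0.104) and peony (0.70 ± 0.104). It also passed upward with Atractylodes (0.45 ± 0.106) and downward with licorice (-0.30 ± 0.115). The Atractylodes call was lost without Atractylodes 500 replicate 2 (adjusted p = 0.2) or 3 (0.184) and without vehicle replicate 1 (0.0515), 2 (0.143) or 3 (0.0665), and the licorice call without Licorice 500 replicate 1 (0.146), 2 (0.0544) or 3 (0.0622) and without vehicle replicate 1 (0.0863) or 3 (0.107). Over the doses it rose with Poria (0.44 ± 0.098) and fell with licorice (-0.78 ± 0.111). TXNIP, an inhibitor of thioredoxin, rose with the dose of Poria (0.24 ± 0.046) and fell with that of licorice (-0.34 ± 0.046). It also passed upward with peony (0.16 ± 0.045), which was lost without Peony 20 replicate 1 (adjusted p = 0.102) or 3 (0.181) and without Peony 500 replicate 1 (0.138) or 2 (0.182). HMOX1, heme oxygenase, rose with the dose of Poria (0.26 ± 0.053), licorice (0.29 ± 0.052) and peony (0.30 ± 0.052). MKI67, a proliferation marker, changed by -1.23 ± 0.092 with wortmannin, and by -0.47 ± 0.091, -0.38 ± 0.09 and -0.23 ± 0.09 with 500 µg/mL of Poria, peony and licorice. The licorice call was lost without Licorice 500 replicate 1 (adjusted p = 0.0545), without Licorice 500 replicate 2 (0.122), without Licorice 500 replicate 3 (0.11), without vehicle replicate 1 (0.0573), without vehicle replicate 2 (0.0654) or without vehicle replicate 3 (0.154). CYP3A4 stood at 0.39 ± 0.0675 CPM with vehicle, and passed in none of the 12 tests of extracts at 500 µg/mL or over dose.

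The lists and genes of these paragraphs were picked for description after their results were seen. In ER chaperones, wortmannin went downward: 6 of 24 measured members rose and 13 fell (6 and 13 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.222 with an estimated correlation), with CALR at -0.67 ± 0.036. In NF-kB targets, 6 of 17 measured members rose and 0 fell (6 and 1 adjusted over the list alone; adjusted p = 0.00119) with angelica at 500 µg/mL, with the chemokine gene CCL20 at 0.86 ± 0.101, while the list did not pass over the doses (adjusted p = 0.329). In p53 targets, 9 of 26 measured members rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 0.000412) with peony at 500 µg/mL, with GDF15 at 0.59 ± 0.061 and the cell cycle inhibitor CDKN1A at 0.29 ± 0.049. In fatty acid and triglyceride synthesis, 0 of 20 measured members rose and 13 fell (0 and 15 adjusted over the list alone; adjusted p = 4.37e-08) with the same extract and dose. In hepatocyte genes, Poria at 500 µg/mL went downward: 8 of 27 measured members rose and 12 fell (8 and 12 adjusted over the list alone; adjusted p = 0.00622, and adjusted p = 0.3 with an estimated correlation), with the transcription factor gene CEBPA at -1.20 ± 0.07. In autophagy and lysosome genes, licorice at 500 µg/mL went upward: 10 of 31 measured members rose and 4 fell (11 and 4 adjusted over the list alone; adjusted p = 0.00571, and adjusted p = 0.195 with an estimated correlation), with SQSTM1 at 0.77 ± 0.038.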
